A study of Homo sapiens with 6 samples.

How the data were processed

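Human pulmonary artery smooth muscle cells (PASMC), the contractile cells of the wall of the lung artery, were compared in 2 groups of 3 libraries. The non-target control group (NTC, replicates 1 to 3) came from cells with a control guide RNA, and the ENG knockout group (ENG_KO, replicates 4 to 6) from cells made with a lentiviral CRISPR construct against ENG. CRISPR uses a guide RNA to direct the Cas9 nuclease to a matching DNA site, where faulty repair of the cut can disrupt the gene. Per the labels' protocols, poly-A RNA was captured with oligo-dT beads, copied with random primers in a strand-preserving kit, and read as 50-base single reads, with the 6 libraries pooled in 1 lane. Replicate numbers were not shared between the groups and no batch was given, so no pairing or batch term was fitted. The labels do not say whether replicates were separate cultures, so every p-value measures only the spread between these libraries, which may be technical. They also do not say whether replicates were separate transductions, or whether both groups came from the same donor cells. A difference of donor, transduction or culture between the groups would coincide with ENG targeting, and no test here can tell them apart.

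The deposited values were log2 normalized expression values per gene, made by the authors. Per the submitters' processing notes, the authors used TopHat2, a spliced read aligner, HTSeq, a read counter, and DESeq2, a package for normalization and testing of counts, with build hg19. No versions are given. The annotation, the filters and the name of the log transformation are not given in the sources used here. In the deposited table, 7096 of the 26440 rows stood at exactly 0 in all 6 libraries, and genes of very low level differed less between libraries than genes of moderate level. Between NTC replicates 1 and 2 the SD of the log2 difference was 0.069 for genes of mean log2 level from -3 to 0, against 0.206 for those from 2 to 4. The values of low genes had thus been drawn together before deposit, and fold changes on this scale understate the change of such genes. No counts or library totals were held, so the depth of each library is unknown and no interval from counting was computed. Values turned back from the log scale have a sum that follows the normalization and is not a depth; the 10 most abundant genes held 7.61% to 8.45% of this sum.

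Rows were handled as follows. In the table, 578 Entrez identifiers stood on more than 1 row, 513 of them with identical values and 65 with different values, and the row with the highest mean was kept, which left 25351 genes. The names of 28 genes had been replaced by numbers, as spreadsheet software does with names that resemble dates, and all 28 were restored through their Entrez identifiers. Genes informative of sex were left out, which left 25244 genes. All 6 value columns were matched to libraries by the sample descriptions and were used. Reads from genes with near-identical copies, such as the ribosomal protein genes, CD24 and the CXCL1 to CXCL3 family, may have been split or dropped in the authors' counting, and values of these genes are uncertain.

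The tests and their settings were fixed before the data were examined. Genes were tested when their mean over the 6 libraries was at least 10 normalized counts (3.32 on the log2 scale), which 13501 genes passed. Differences were fitted with limma 3.58.1 in R 4.3.3, using moderated tests with an intensity trend on all 6 libraries and 4 residual degrees of freedom, and Benjamini-Hochberg adjustment over the genes tested. Every adjusted p of a gene comes from this limma fit, or where stated from the same fit without ENG_KO replicate 6 or under another alternative named there. A gene was called at an adjusted p under 0.05, and a separate count required an absolute log2 fold change of at least 1. Gene lists (24 lists of pathways and functions, and 5 lists of markers of other cell types) were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists with at least 5 tested members. Camera compares the genes of a list with all other genes. The correlation estimated from the data and fry were alternatives. The estimated correlation rests on at most 4 residual degrees of freedom and is imprecise, so a list not called with it is not shown to be unchanged. The directional p of fry tests whether the genes of a list move on balance in 1 direction. It does not compare the list with other genes. Counts within a list are given from the adjustment over all genes and adjusted over the list alone.

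The genes named in the text follow a rule fixed in advance. ENG is named, as are ID1, ID2, ID3, SMAD6, SMAD7, CTGF, ACTA2, TAGLN, CNN1, MYH11 and the receptors ACVRL1, BMPR2, TGFBR1, TGFBR2 and TGFBR3, whatever their test. Named next are the 10 largest rises and the 10 largest falls among called genes with a mean at or above the median of the tested genes (9.51) and with every ENG_KO library beyond every NTC library. This part leaves out names that begin with LOC, LINC, MIR, SNOR, SNHG, RNU, RN7 or ENSG, names with -AS, XIST and Y-linked genes. From each gene list, up to 2 called members that rose and 2 that fell with the smallest adjusted p are named, or the member with the smallest p where none was called, and from each marker list the member with the highest mean. After the data were seen, the parts on largest changes and on list members were applied a second time to the fit without ENG_KO replicate 6. Some genes that the rule takes in are not reported here. Members outside the rule are named with the statement that they were chosen after their values were seen.

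Alternatives fixed in advance were no filter, a filter at 50 normalized counts, limma without the trend, with robust shrinkage and with array weights, quantile normalization, re-centring by a trimmed mean, scaling to the same total, pseudocounts of 0.5 and 5 on back-transformed values, an unshrunken least squares fit, and leaving out each library in turn. For lists, camera with an estimated correlation, fry and camera on ranks were added to these. Chosen after the data were seen were fits with the trend of each library over transcript length removed, with the trends over length and GC content removed, and with these trends removed and ENG_KO replicate 6 left out. Trends were removed as a lowess curve (span 0.3) of each library's deviation from the mean over libraries. For replicate 6, slopes with no change were taken from 100 simulations with unchanged values in that library and from each NTC library in its place. Length and GC content came from the longest transcript of each gene in GENCODE 29 and were found for 13338 of the tested genes (98.8%). The guide was searched as an exact match in the annotated transcripts of GENCODE 29, and its place on GRCh38 was taken from the exon coordinates. Sequence outside these transcripts and sites with mismatches were not searched. The authors' build was hg19, and no coordinate was converted.

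The scripts were tested on simulated data of 13501 genes with known changes, drawn with each gene's spread in the 5 libraries other than ENG_KO replicate 6 and with added random spread for that library. For the comparison of all 6 libraries, 4.7% of genes changed by 0.5 on the log2 scale were recovered, 47.8% of those changed by 1 and 89.6% of those changed by 2, with 0 false calls. For the comparison without ENG_KO replicate 6 the shares were 82.8%, 100% and 100%, with 2 false calls. The spread added to replicate 6 was independent between genes, whereas its real deviation went with transcript length and GC content. The recovery and false calls simulated for all 6 libraries therefore need not hold for the real data, least of all for short or long transcripts. Data handling and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and limma's weights used statmod 1.5.0.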

Results

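RNA-seq profiles of human pulmonary artery smooth muscle cells were compared between non-target control cells (NTC, 3 libraries) and ENG knockout cells (ENG_KO, 3 libraries). ENG encodes endoglin, a co-receptor for ligands of the TGF-beta and BMP families, and carriers of disrupted ENG can develop hereditary hemorrhagic telangiectasia. The comparison asks which transcripts differ between the ENG-targeted and the control cells. The labels do not say whether the groups shared donor cells or how many transductions were made. A difference of donor, transduction or culture cannot be told apart from an effect of ENG here, however small the p-value. Levels are the deposited log2 normalized values, differences are ENG_KO minus NTC on that scale, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over 13501 genes. The depth of the libraries is unknown because no counts were held.

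The guide, TGCCGACGACGCCATGACCC, matched ENG and no other annotated gene. On GRCh38 with GENCODE 29 it lies on chromosome 9 from 127824330 to 127824349, in coding sequence of exon 8 of the 15 exons of ENST00000373203 (exon bounds 127824304 and 127824446), followed by the bases TGG. The gene spans 127815012 to 127854756 on the minus strand. Only exact matches within annotated transcripts were searched, so similar sites elsewhere in the genome were not assessed.

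ENG mRNA was lower in all 3 ENG_KO libraries than in every NTC library. The NTC libraries stood at 13.17, 13.13 and 13.09, and ENG_KO replicates 4, 5 and 6 at 12.52, 12.59 and 12.88. The group means were 13.13 ± 0.04 (SD, n = 3) and 12.66 ± 0.19 (SD, n = 3), a difference of -0.47 (SE 0.12), or 0.724 times the control level. This difference did not pass the test with all 6 libraries (adjusted p = 0.174), and without ENG_KO replicate 6 ENG fell by 0.57 (SE 0.04, adjusted p = 2.63e-10). A guide that disrupts the reading frame need not remove the transcript, so the mRNA level does not measure the loss of the protein.

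ENG_KO replicate 6 stood apart from the other 5 libraries, and this bears on each count given here. The SD over genes of the log2 difference was 0.607 to 0.663 in the 5 pairs that contain it, against 0.111 to 0.128 in the other 4 pairs within a group and 0.244 to 0.257 in the other 6 pairs between groups. Its difference from the mean of replicates 4 and 5 went with transcript length. The median was 0.80 for transcripts under 1000 bases and -0.70 for those over 8000 bases, whereas the medians of replicates 4 and 5 minus NTC were between -0.02 and 0.01 in all 5 length classes. Counts of the gene lists are therefore given with all 6 libraries, as fixed in advance, and beside them without ENG_KO replicate 6. Genes given with a value from the fit without that library alone were not called with all 6.

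**Figure D1:**
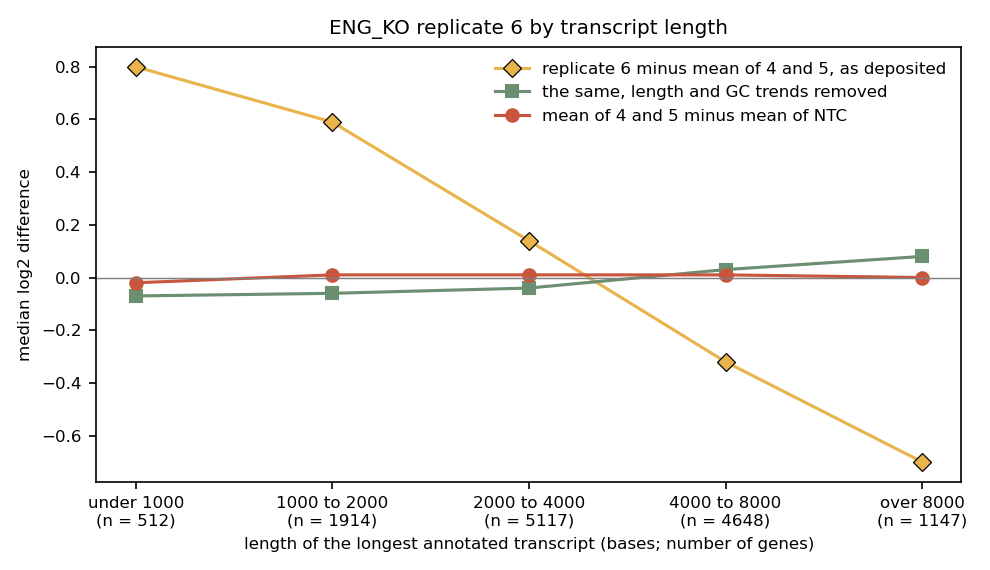
Median log2 difference (y axis) of genes grouped by the length of their longest annotated transcript in bases (x axis, with the number of genes). Diamonds are ENG_KO replicate 6 minus the mean of replicates 4 and 5, squares the same after removal of length and GC trends, and circles the mean of replicates 4 and 5 minus the NTC mean; the diamonds run from 0.80 to -0.70.

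With all 6 libraries, 92 genes were higher and 130 lower in ENG_KO, 222 in total, of which 114 changed by at least 2-fold. Among called genes with a mean level of at least 9.51 and every ENG_KO library beyond every NTC library, the largest rise was in C15orf52 (1.60, SE 0.09, adjusted p = 0.00277, 3.03 times the control). IL6, an inflammatory cytokine, rose by 1.47 (SE 0.18, adjusted p = 0.0167), and PLAU, the urokinase protease that activates plasminogen, by 1.38 (SE 0.19, adjusted p = 0.0226). GREM1, a secreted antagonist of BMP ligands, rose by 1.30 (SE 0.20, adjusted p = 0.0378). The next rises were in TMEM158 (1.28), F2RL1, a protease-activated receptor (1.22), DNER, a Notch-related transmembrane protein (1.18), FAM107B (1.09), KYNU, an enzyme of tryptophan breakdown (0.97), and POU2F2, a transcription factor (0.95), with adjusted p from 0.00312 to 0.0281. After removal of length and GC trends the difference of KYNU was larger, 1.36, but so was its SE, 0.36 against 0.10. Its call was lost (adjusted p = 0.112). The length used for KYNU was that of its longest annotated transcript, 15316 bases. As deposited its ENG_KO libraries lay close together, at 10.54, 10.54 and 10.71, so this loss came with the trend removal.

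The largest falls among such genes were in PTGIS, which makes prostacyclin, a dilator of the lung circulation, and SULF1, which removes sulfate groups from heparan sulfate. PTGIS fell by 2.06 (SE 0.10, adjusted p = 0.00277), to 0.24 times the control, and SULF1 fell by 2.02 (SE 0.13, adjusted p = 0.00312). GBP4, an interferon-inducible GTPase, fell by 1.90 (SE 0.16, adjusted p = 0.00495), CPXM2 fell by 1.46, and IGFBP5, a binding protein for insulin-like growth factors, fell by 1.40. CD24 fell by 1.20, UNC5B, a netrin receptor, fell by 1.17, and GPC3, a cell-surface proteoglycan, fell by 1.10. DIRAS3 fell by 1.05 and COL16A1, a collagen chain, fell by 1.01. The adjusted p of these genes ranged from 0.00277 to 0.0226, and all 20 genes had every ENG_KO library beyond every NTC library, an arrangement that the rule for naming them required and that chance gives for 10% of genes.

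**Figure D2:**
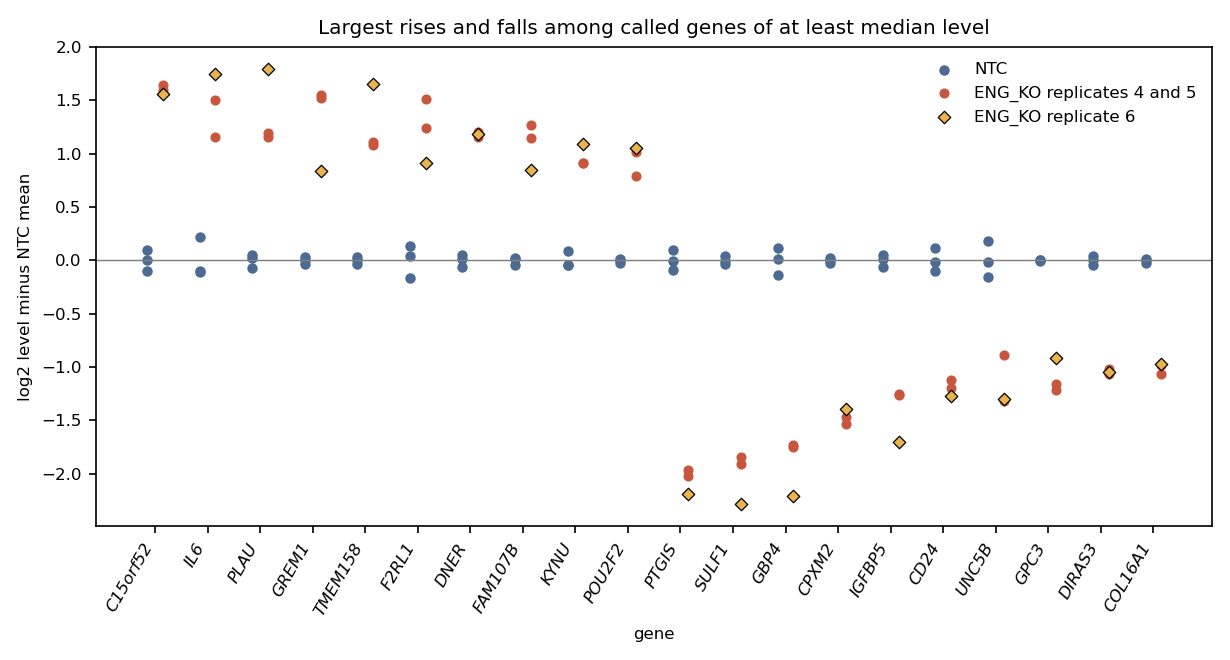
Log2 level minus the NTC mean (y axis) in each library for the 10 largest rises and the 10 largest falls among called genes with a mean level of at least 9.51 and every ENG_KO library beyond every NTC library (x axis). Each point is a library; ENG_KO replicate 6 (diamonds) lies on the same side of the NTC libraries as replicates 4 and 5 for all 20 genes.

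The count of changed genes depended on which libraries entered. It was 38, 38 and 31 without NTC replicates 1, 2 and 3, 92 and 98 without ENG_KO replicates 4 and 5, and 2713 without ENG_KO replicate 6; of the 20 genes named above from the fit of all 6 libraries, C15orf52, DNER, PTGIS, SULF1 and CPXM2 were called in all 6 of these fits. The 2713 genes without ENG_KO replicate 6 were 1474 higher and 1239 lower, of which 135 changed by at least 2-fold, and they included all 222 genes called with 6 libraries, each in the same direction. Their median absolute log2 difference was 0.28, against 1.00 for the 222. After removal of length and GC trends, an alternative chosen after the data were seen, 641 genes were called with all 6 libraries, and all 641 were also called, in the same direction, without replicate 6.

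Without ENG_KO replicate 6, among called genes with a mean level of at least 9.51 and replicates 4 and 5 beyond every NTC library, the largest rise was in DSG2, a desmosomal cadherin (2.01, SE 0.05, adjusted p = 1.86e-18), and CDH11, a mesenchymal cadherin, rose by 1.58 (SE 0.05). These differences were 1.61 with all 6 libraries (adjusted p = 0.103) and 1.27 (adjusted p = 0.0921). NPPB, which encodes a natriuretic peptide, fell by 1.40 (SE 0.07), and CALB2, a calcium-binding protein, fell by 1.13 (SE 0.05). In the fit of all 6 libraries NPPB differed by -1.03 (adjusted p = 0.291) and CALB2 by -0.91 (adjusted p = 0.110). The other 8 largest rises and 8 largest falls among these genes were in genes already named.

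Genes that respond to BMP ligands through SMAD1 and SMAD5 were lower on balance. Of 14 tested members, 1 was higher (GREM1) and 3 were lower with all 6 libraries, and the median was -0.15; adjusted over the list alone the counts were 1 and 6. SMAD6, an inhibitory SMAD induced by BMP signaling, fell by 0.92 (SE 0.09, adjusted p = 0.0086), and ID2, a BMP-induced inhibitor of transcription factors, fell by 0.76 (SE 0.10, adjusted p = 0.0216). The list test gave adjusted p = 0.0028 and adjusted p = 0.513 with an estimated correlation. Once ENG_KO replicate 6 was left out, 2 members were higher and 8 lower, also adjusted over the list alone, with a median of -0.34 (adjusted p = 8.83e-06, and adjusted p = 0.575 with an estimated correlation). There ID1 fell by 0.40 (SE 0.04, adjusted p = 1.89e-07), ID3 fell by 0.28 (SE 0.04, adjusted p = 5.03e-05), SMAD7 fell by 0.44 (SE 0.05) and ATOH8 fell by 0.80 (SE 0.06), while BMPER rose by 0.20 (SE 0.05), against 0.04 with all 6 libraries (adjusted p = 0.900). BMPER in replicate 6, at 9.59, lay below every NTC library (9.82 to 9.99). With length and GC trends removed BMPER differed by 0.12 and was not called (adjusted p = 0.451).

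ID1 and ID3 went in opposite directions within the ENG_KO group. In replicates 4 and 5 ID1 was on average 0.40 below the NTC mean, and in replicate 6 it was 0.41 above it. For ID3 the corresponding differences were -0.28 and 0.71. The group differences over all 6 libraries were -0.13 (SE 0.23, adjusted p = 0.755) for ID1 and 0.05 (SE 0.28, adjusted p = 0.922) for ID3, and SMAD7 differed by -0.47 (SE 0.09, adjusted p = 0.088).

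**Figure D3:**
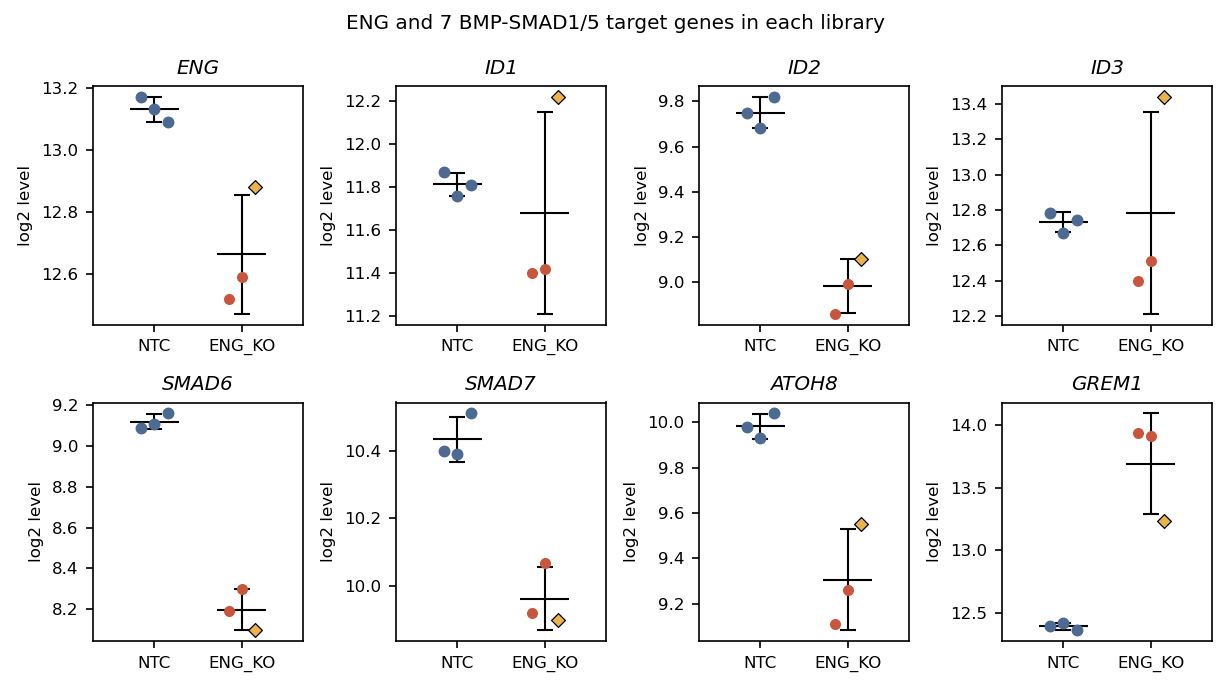
Log2 level (y axes, each with its own range) of ENG and 7 BMP-SMAD1/5 target genes in the 3 NTC and 3 ENG_KO libraries (x axes). Points are libraries, horizontal lines the group means and bars the SD over 3 libraries; the diamond is ENG_KO replicate 6, which lies above every NTC library for ID1 and ID3 and on the side of replicates 4 and 5 for the other 6 genes.

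Receptors, co-receptors and SMADs of the TGF-beta and BMP pathways were tested for 21 genes. SMAD6 was the 1 call with all 6 libraries, and adjusted over the list alone 5 were lower; the list had a median of -0.26 and adjusted p = 0.00136, with adjusted p = 0.649 with an estimated correlation. The median was -0.04 without ENG_KO replicate 6, and the list was not called (adjusted p = 0.0501), with 2 members higher and 7 lower. In that fit TGFBR3, the co-receptor betaglycan, rose by 0.63 (SE 0.06, adjusted p = 2.02e-08) and RGMB, a BMP co-receptor, rose by 0.50 (SE 0.04), while TGFBR1 fell by 0.15 (SE 0.05, adjusted p = 0.0398). ACVRL1, BMPR2 and TGFBR2, receptors that act with endoglin, differed by -0.12, -0.01 and 0.05 there (adjusted p = 0.587, 0.912 and 0.481). Over all 6 libraries these receptors differed by 0.06, -0.46 and -0.16, with -0.43 for TGFBR1 and 0.25 for TGFBR3 (adjusted p from 0.613 to 0.850). TGFBR3 went the other way in replicate 6, which at 8 lay below every NTC library (8.49 to 8.57). With length and GC trends removed and all 6 libraries, TGFBR3 differed by 0.42 and was not called (adjusted p = 0.251). ACVRL1 was a low gene, at 3.36 to 4.07, near the filter on low values, whereas BMPR2 and TGFBR2 had NTC means of 12.78 and 14.05. Without replicate 6 the SE was 0.13 for ACVRL1, against 0.05 for BMPR2 and 0.04 for TGFBR2. The lack of a call for ACVRL1 therefore decides little. Of 18 ligands, latent binding proteins and antagonists, GREM1 was the only call with all 6 libraries, and adjusted over the list alone 1 was higher and 1 lower. Without replicate 6, 4 were higher and 3 lower (5 and 3 adjusted over the list alone): INHBA rose by 0.43, TGFB2 fell by 0.73 and LTBP3 fell by 0.32.

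Genes that respond to TGF-beta through SMAD2 and SMAD3 were also lower on balance. Of 24 members 1 was called with all 6 libraries, POSTN, a matrix protein, which fell by 1.00 (SE 0.12, adjusted p = 0.0141), and adjusted over the list alone 5 were lower. The median was -0.22 (adjusted p = 0.00136, and adjusted p = 0.513 with an estimated correlation). In the fit without ENG_KO replicate 6, 2 were higher and 13 lower, also adjusted over the list alone (adjusted p = 9.13e-05, and adjusted p = 0.575 with an estimated correlation). There CTGF fell by 0.38 (SE 0.04, adjusted p = 4.36e-07) and IGFBP3 fell by 0.52 (SE 0.05), whereas THBS1 rose by 0.25 and HMOX1 by 0.17. With all 6 libraries THBS1 differed by -0.01 (adjusted p = 0.991) and HMOX1 by 0.34 (adjusted p = 0.570). THBS1 in replicate 6, at 13.74, lay below every NTC library (14.2 to 14.32). With length and GC trends removed neither was called (THBS1 0.20, adjusted p = 0.185, and HMOX1 0.12, adjusted p = 0.400).

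Collagens and matrix proteins were lower in ENG_KO for more members than they were higher. Over all 6 libraries 4 of 36 members were lower and the other 32 were not called, with 6 lower adjusted over the list alone and a median of -0.25 (adjusted p = 8.04e-05, and adjusted p = 0.513 with an estimated correlation). FBLN2, an elastic fiber protein, fell by 0.92 (SE 0.09, adjusted p = 0.00872), and COL16A1 and POSTN were among the 4. Without ENG_KO replicate 6, 5 members were higher and 20 lower (7 and 22 adjusted over the list alone; adjusted p = 8.83e-06, and adjusted p = 0.575 with an estimated correlation). COL6A3, a chain of collagen VI, rose there by 0.81 (SE 0.06) and LAMA4, a laminin chain, by 0.27, against 0.53 (adjusted p = 0.549) and 0.16 (adjusted p = 0.613) with all 6 libraries. LAMA4 in replicate 6, at 13.37, lay below every NTC library (13.4 to 13.49). With length and GC trends removed COL6A3 was called higher (0.72, adjusted p = 0.0113) and LAMA4 was not called (0.31, adjusted p = 0.0563). Among 21 matrix proteases and inhibitors, MMP3, a protease of matrix proteins, rose by 1.88 (SE 0.22, adjusted p = 0.0141) with all 6 libraries, as did PLAU, and adjusted over the list alone 2 were higher and 1 lower. Without replicate 6, 3 were higher and 8 lower (4 and 10 adjusted over the list alone), among them SERPINE2, which fell by 0.55, and ADAMTS2, which fell by 0.27; the list itself was not called with all 6 libraries (adjusted p = 0.797) or without replicate 6 (adjusted p = 0.337).

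The tested contractile genes of smooth muscle did not move together. Of 28 genes on this list 22 were tested, so the list test leaves out part of the contractile genes. MYOCD and LMOD1, named after their values were seen, were tested at low NTC means of 5.01 and 4.84. None of 22 members was called with all 6 libraries by limma or by the unshrunken fit, 1 was higher and 2 lower at an unadjusted p under 0.05, and 1 was higher and 1 lower adjusted over the list alone. The list had a median of -0.10 and a mean of 0.03 (adjusted p = 0.797). With length and GC trends removed the median was 0.01, and camera did not call the list (adjusted p = 0.684) while fry did (adjusted p = 0.0359). ACTA2, TAGLN, CNN1 and MYH11, markers of the contractile state, differed by 0.17 (SE 0.15), 0.21 (SE 0.25), 0.16 (SE 0.19) and -0.23 (SE 0.09), with adjusted p from 0.496 to 0.653. Leaving out ENG_KO replicate 6, they differed by 0.02, -0.08, -0.05 and -0.23, with adjusted p from 0.213 to 0.793. MYH11 was a low gene, at 3.45 to 3.81, near the filter on low values. Its SE without replicate 6 was 0.13, so its lack of a call decides little. In that fit MYLK, the myosin light chain kinase, rose by 1.04 (SE 0.06, adjusted p = 2.13e-11) and ACTG2, the enteric smooth muscle actin, by 0.64 (SE 0.08), while CSRP1 fell by 0.52 and TPM1 fell by 0.24; these 4 were the only calls, also adjusted over the list alone. With all 6 libraries MYLK differed by 0.61 (SE 0.36, adjusted p = 0.613), and its level in replicate 6, 8.11, lay below every NTC library (8.24 to 8.43). The longest transcript of MYLK has 10027 bases. With length and GC trends removed MYLK differed by 0.82 and was not called (adjusted p = 0.0601).

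Among 22 ion channels and vasoactive receptors, CACNA1H, a T-type calcium channel, fell by 0.89 (SE 0.09, adjusted p = 0.0085) with all 6 libraries and was the only call, with 2 lower adjusted over the list alone. CACNA1H was a low gene, at 4.51 to 4.62 in NTC and 3.61 to 3.75 in ENG_KO, and the size of its fall is uncertain on this scale. The median of the list was -0.15 (adjusted p = 0.0376, and adjusted p = 0.683 with an estimated correlation). Its call was lost without a filter (adjusted p = 0.527), with both trends removed (adjusted p = 0.260), and with the filter of 50 normalized counts, quantile normalization, the same total per library or ranks (adjusted p from 0.0517 to 0.0799). In the fit without ENG_KO replicate 6, 6 were higher and 7 lower (8 and 8 adjusted over the list alone), with a median of 0.06, a mean of -0.04 and no call (adjusted p = 0.965). ABCC9, a subunit of potassium channels, rose there by 0.66 and ATP2B4, a calcium pump, by 0.51, while TRPV4, a calcium-permeable channel, fell by 0.64. With all 6 libraries ABCC9 differed by 0.28 (adjusted p = 0.643) and ATP2B4 by 0.13 (adjusted p = 0.809). Replicate 6 lay below every NTC library for both, at 6.48 against an NTC mean of 6.96 (SD 0.06) and at 13.31 against 13.92 (SD 0.01). The longest transcripts of both are long, 8293 and 8968 bases. With length and GC trends removed and all 6 libraries, ABCC9 was called higher (0.58, adjusted p = 0.0204). ATP2B4 was not called there (0.35, adjusted p = 0.229). Of 12 tested genes of pulmonary hypertension and telangiectasia, none was called with all 6 libraries by limma or by the unshrunken fit, also adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05. Without replicate 6, 3 were higher and 2 lower, also adjusted over the list alone: RASA1 rose by 0.48, CAV1, which encodes caveolin, by 0.35 and KLF2 was the remaining rise, while SMAD9 fell by 0.65 beside ENG. KLF2 is named after its value was seen. RASA1 differed by 0.14 with all 6 libraries (adjusted p = 0.788), with replicate 6 at 11.24, below every NTC library (11.75 to 11.85). For CAV1 and SMAD9 the differences were 0.25 (adjusted p = 0.548) and -0.94 (adjusted p = 0.209). With length and GC trends removed RASA1 differed by 0.26 and was not called (adjusted p = 0.470).

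Inflammatory and interferon-induced genes went in opposite directions. Of 26 NF-kB and cytokine genes IL6 was the only call with all 6 libraries, with 11 higher and 2 lower adjusted over the list alone and a median of 0.24 (adjusted p = 0.00136, and adjusted p = 0.513 with an estimated correlation). After ENG_KO replicate 6 was left out, 15 were higher and 4 lower (17 and 7 adjusted over the list alone; adjusted p = 1.53e-05, and adjusted p = 0.575 with an estimated correlation). CXCL1, a neutrophil attractant, rose there by 0.64 (SE 0.05), whereas CCL2 and CCL7, which attract monocytes, fell by 0.57 and fell by 0.48. Of 27 interferon-stimulated genes XAF1 was the only call with all 6 libraries and fell by 0.63 (SE 0.10, adjusted p = 0.0452), with 2 lower adjusted over the list alone and a median of -0.24 (adjusted p = 0.00136, and adjusted p = 0.513 with an estimated correlation). Without replicate 6, 1 was higher and 16 lower (1 and 17 adjusted over the list alone; adjusted p = 1.34e-06, and adjusted p = 0.575 with an estimated correlation), among them IFI6, which fell by 0.44, and the rise was in ISG20 (0.51). IFI6 went the other way in replicate 6, which at 10.28 lay above every NTC library (9.39 to 9.58), and differed by -0.03 with all 6 libraries (adjusted p = 0.969). For ISG20 the difference was 0.82 (adjusted p = 0.343). The longest transcript of IFI6 is short, 841 bases. With length and GC trends removed IFI6 was called lower with all 6 libraries (-0.36, adjusted p = 0.044).

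Genes of cell division were slightly higher. In the fit of all 6 libraries no member of the G2 and mitosis list (33 genes) or the S phase list (34 genes) was called by limma or by the unshrunken fit, also adjusted over the list alone, and 2 and 3 members were higher at an unadjusted p under 0.05. The medians were 0.11 and 0.18 (adjusted p = 0.0044 and 0.000316; adjusted p = 0.587 and adjusted p = 0.513 with an estimated correlation), and the G2 and mitosis call was lost without ENG_KO replicate 4 (adjusted p = 0.231). Without ENG_KO replicate 6, 25 G2 and mitosis genes were higher and 0 lower, with 31 higher adjusted over the list alone, and 18 S phase genes were higher and 0 lower, with 23 higher adjusted over the list alone. Of the members not called there, 0 were lower at an unadjusted p under 0.05 in either list. The list tests gave adjusted p = 1.19e-09 and 9.45e-06, and adjusted p = 0.575 for both with an estimated correlation. The rises were small: FOXM1, a transcription factor of mitotic genes, rose by 0.33 (SE 0.05), AURKA, a mitotic kinase, by 0.30 (SE 0.05), and RRM2, a subunit of ribonucleotide reductase, by 0.27 (SE 0.04).

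Of the stress and metabolism lists, none of 27 p53 target genes was called with all 6 libraries by limma or by the unshrunken fit; 1 was lower adjusted over the list alone and 6 at an unadjusted p under 0.05. That list had a median of -0.06 and was not called with all 6 libraries (adjusted p = 0.105). It was called lower with all 6 after quantile normalization (adjusted p = 0.0442), with array weights (adjusted p = 0.00826), and with length trends (adjusted p = 0.00954) or length and GC trends (adjusted p = 0.00142, and adjusted p = 0.469 with an estimated correlation) removed. Without ENG_KO replicate 6, 3 p53 targets were higher and 9 lower (3 and 12 adjusted over the list alone; adjusted p = 0.0042, and adjusted p = 0.575 with an estimated correlation), among them TP53INP1, which fell by 0.64. Of 27 hypoxia and glycolysis genes, 32 genes of the ATF4 and unfolded protein responses and 25 cholesterol synthesis genes, none was called with all 6 libraries by limma or by the unshrunken fit, also adjusted over the list alone. At an unadjusted p under 0.05, 2 were higher in the first list, 1 was higher and 4 lower in the second, and 1 was higher and 1 lower in the third. Without replicate 6, 7 hypoxia and glycolysis genes were higher and 0 lower, with 8 higher adjusted over the list alone, including NDRG1 (0.31) and HK2 (0.29, against 0.15 with all 6 libraries, adjusted p = 0.616). HK2 in replicate 6, at 11.92, lay below every NTC library (12.03 to 12.12). With length and GC trends removed HK2 was not called (0.23, adjusted p = 0.119) and NDRG1 was called higher (0.36, adjusted p = 0.0388). The hypoxia list was called with all 6 libraries (median 0.16, adjusted p = 0.00855, and adjusted p = 0.587 with an estimated correlation), and the call was lost without ENG_KO replicate 5 (adjusted p = 0.0688) and after quantile normalization (adjusted p = 0.0774). The ATF4 list had a median of 0.03 and a mean of -0.02 with all 6 libraries and was not called (adjusted p = 0.673). Once replicate 6 was left out, 3 of its genes were higher and 11 lower (4 and 12 adjusted over the list alone; median -0.07, adjusted p = 0.00801, and adjusted p = 0.733 with an estimated correlation). ASNS, which makes asparagine, fell by 0.58 and PSAT1, of serine synthesis, fell by 0.45 there. Cholesterol synthesis genes had 4 higher and 2 lower members without replicate 6, with 5 and 2 adjusted over the list alone, and were not called with all 6 libraries (adjusted p = 0.503) or without replicate 6 (adjusted p = 0.409).

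Among 30 angiogenic and vascular growth factor genes, 15 were higher and 4 lower without ENG_KO replicate 6, also adjusted over the list alone (median 0.11, adjusted p = 0.0121, and adjusted p = 0.575 with an estimated correlation). HBEGF, an EGF-family growth factor, rose by 0.55 (SE 0.04), VEGFC, a growth factor for lymphatic vessels, by 0.45, and EDN1, the vasoconstrictor endothelin, fell by 0.69 (SE 0.06). Over all 6 libraries the list had a median of -0.05 and was not called (adjusted p = 0.797). No member of the angiogenic, YAP-TEAD or Notch lists was called there by limma or by the unshrunken fit. Adjusted over the list alone, 2 were higher and 2 lower in the first, 1 and 4 in the second, and 0 and 1 in the third, and at an unadjusted p under 0.05 the numbers were 6 and 5, 2 and 4, and 1 and 1. YAP-TEAD targets (24) had a median of -0.25 with all 6 libraries (adjusted p = 0.0206, and adjusted p = 0.638 with an estimated correlation) and -0.03 without replicate 6 (adjusted p = 0.218), with 5 higher and 6 lower in that fit, also adjusted over the list alone. Notch pathway genes (14) had 4 higher and 3 lower members without replicate 6 (5 and 3 adjusted over the list alone), among them NOTCH1, which rose by 0.34, and NOTCH3, which fell by 0.22. With all 6 libraries these differed by 0.17 (adjusted p = 0.615) and -0.41 (adjusted p = 0.504). NOTCH1 in replicate 6, at 10.24, lay below every NTC library (10.31 to 10.46). With length and GC trends removed NOTCH1 was called higher (0.32, adjusted p = 0.0376) and NOTCH3 was not called (-0.27, adjusted p = 0.0760). The Notch list was not called with all 6 libraries (adjusted p = 0.732) or without replicate 6 (adjusted p = 0.940).

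Homeobox and positional identity genes (25) had 1 call with all 6 libraries, TCF21, a transcription factor of mesenchymal cells, which rose by 0.76 (SE 0.10, adjusted p = 0.0202), with 6 higher and 1 lower adjusted over the list alone. The list was called with all 6 libraries (median 0.22, adjusted p = 0.0183, and adjusted p = 0.638 with an estimated correlation) and not without ENG_KO replicate 6 (adjusted p = 0.121), where 10 were higher and 5 lower (11 and 5 adjusted over the list alone). That call was also lost without a filter on low values (adjusted p = 0.0725) and with both trends removed (adjusted p = 0.684). Without replicate 6 HOXC10 rose by 0.38, and HOXC8 fell by 0.36. Of 15 genes next to ENG on chromosome 9, DNM1, which encodes a dynamin, rose by 1.07 (SE 0.10, adjusted p = 0.00681) with all 6 libraries and by 1.09 without replicate 6. In the fit without replicate 6 CIZ1 also rose, by 0.12, and PIP5KL1 fell by 0.56, with 2 higher and 1 lower also adjusted over the list alone. That list had a median of 0.24 with all 6 libraries (adjusted p = 0.0165, and adjusted p = 0.652 with an estimated correlation) and 0.04 without replicate 6 (adjusted p = 0.337), and its call was lost with both trends removed (adjusted p = 0.102).

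Nuclear genes of the respiratory chain (37) and ribosomal protein genes (38) were called higher with all 6 libraries, each with a median of 0.32 (adjusted p = 0.000516 and 0.000794; adjusted p = 0.683 and adjusted p = 0.701 with an estimated correlation). With length and GC trends removed the medians were 0.14 and 0.13, and the first list was still called (adjusted p = 0.00359, and adjusted p = 0.640 with an estimated correlation) and the second was not (adjusted p = 0.0751). The longest annotated transcript, whose length was used, need not be the expressed one. For RPL37 it has 7686 bases, and the difference went from 0.32 to 0.55 (SE 0.57) on trend removal. For RPS28, with 1523 bases, the difference went from 0.23 to -0.04. The medians that remained may therefore hold bias that the trend removal left. No single member was called with all 6 libraries by limma or by the unshrunken fit, and 0 passed an unadjusted p under 0.05. Leaving out ENG_KO replicate 6 gave medians of 0.01 (adjusted p = 0.965) and -0.04 (adjusted p = 0.0193, and adjusted p = 0.628 with an estimated correlation), the second in the opposite direction. In that fit 0 respiratory chain genes were called, with 2 at an unadjusted p under 0.05, and 2 ribosomal protein genes, RPL37 and RPS28, were lower (0 adjusted over the list alone).

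Markers of other cell types were measured to describe what the cultures held. EGFL7 was the most abundant of 10 tested endothelial markers, at 9.53 ± 0.05 (SD, n = 3) in NTC, and THY1, at 13.82 ± 0.04, of 12 fibroblast markers. For pericyte, epithelial and leukocyte markers the most abundant were ANGPT1 (11.54), KRT18 (11.49) and CD68 (11.77). Tested were 10 of 15 endothelial, 12 of 15 fibroblast, 7 of 9 pericyte, 5 of 11 epithelial and 3 of 10 leukocyte markers. The level of 1 marker does not show that its cell type was present. With all 6 libraries CDH5 and FLT1 fell among endothelial markers, PI16 fell and TCF21 rose among fibroblast markers, and MCAM rose among pericyte markers; CDH5, FLT1, PI16 and MCAM are named after their values were seen. Adjusted over the list alone, 3 endothelial markers were higher and 3 lower, with a median of 0.02, 1 fibroblast marker was higher and 1 lower, and 1 pericyte marker was higher. No marker list was called with all 6 libraries (adjusted p from 0.354 to 0.894). Without ENG_KO replicate 6 the endothelial list was called lower (2 higher and 4 lower of 10, 3 and 4 adjusted over the list alone, median -0.13, adjusted p = 0.0344, and adjusted p = 0.575 with an estimated correlation). The fibroblast, pericyte and epithelial lists were not called in that fit (adjusted p from 0.0779 to 0.329), and the leukocyte list, with 3 tested members, was too short for a list test. There 2 of 12 fibroblast markers were higher and 4 lower, and 3 of 7 pericyte markers were higher and 2 lower, also adjusted over each list alone. Of 5 epithelial markers 1 was lower (2 adjusted over the list alone), and of 3 leukocyte markers 1 was higher.

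Over all lists, 15 of 28 were called with all 6 libraries and 13 without ENG_KO replicate 6, of which 8 were called in both in the same direction and 1, the ribosomal proteins, in opposite directions. Some lists share members, such as COL1A1, COL1A2, FN1 and POSTN in the TGF-beta-SMAD2/3 and matrix lists. SMAD6, SMAD7, SMAD9 and BAMBI are in both the BMP target and the receptor lists. The calls of such lists are not independent. With an estimated correlation none was called, the lowest adjusted p being 0.513 with all 6 libraries and 0.575 without replicate 6. That correlation was estimated from at most 4 residual degrees of freedom, so the lack of a call there decides little. With fry 3 lists were called with all 6 libraries, all lower: BMP-SMAD1/5 targets (adjusted p = 0.0162), p53 targets (adjusted p = 0.0162) and TGF-beta-SMAD2/3 targets (adjusted p = 0.0246). Without replicate 6 fry called 5 lists. BMP-SMAD1/5 targets, endothelial markers and fibroblast markers were lower and pericyte markers higher (adjusted p = 0.0382 for each), and interferon-stimulated genes were lower (adjusted p = 0.0476). The fry calls of the p53 and TGF-beta-SMAD2/3 targets were lost there (adjusted p = 0.0542 and 0.0599). With length and GC trends removed, chosen after the data were seen, fry called more lists with all 6 libraries than in either fit. These included the receptor, collagen and matrix, interferon and chromosome 9 lists and the BMP-SMAD1/5 targets (adjusted p = 0.0164 for each). Contractile genes (adjusted p = 0.0359) were also called, and NF-kB genes were not (adjusted p = 0.0652).

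**Figure D4:**
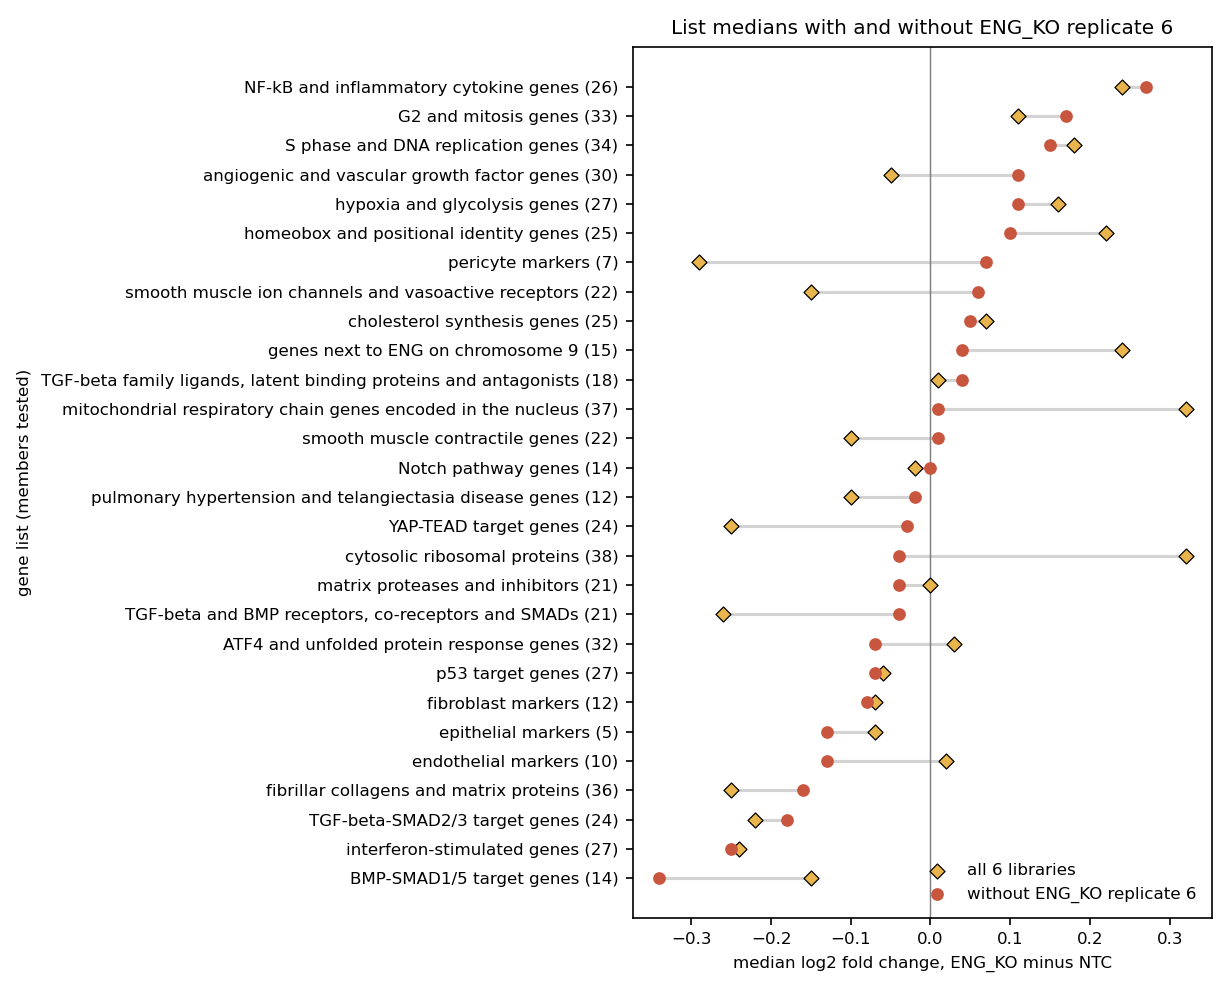
Median log2 fold change of ENG_KO minus NTC (x axis) for the 28 tested gene lists (y axis, with the number of members tested). Diamonds are medians with all 6 libraries and circles those without ENG_KO replicate 6; ribosomal and respiratory chain genes move from 0.32 to -0.04 and 0.01, while the BMP-SMAD1/5 targets move from -0.15 to -0.34.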

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

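The fits with length or GC trends removed were chosen after the data were seen, and the other settings were planned. The edgeR and DESeq2 tests were not run because the deposited values are not counts. Under the settings without a filter, without the trend, with robust shrinkage, after quantile normalization, re-centring or scaling to the same total, and with either pseudocount, the count of 222 genes lay between 206 and 227. It was 124 at the filter of 50 normalized counts (56 higher, 68 lower), where 11630 genes were tested, and 128 with the unshrunken fit (53 and 75; 61 at 2-fold or more), of which 107 were among the 222. With array weights, which gave ENG_KO replicate 6 a weight of 0.028 against 1.451 to 5.721 for the others, it was 2320 (1176 and 1144). It was 423 with length trends removed (194 and 229), 641 with length and GC trends removed (296 and 345) and 3544 with these removed and ENG_KO replicate 6 left out (1880 and 1664). Leaving out 1 library at a time gave 31 to 2713 genes, 11 to 1474 higher and 20 to 1239 lower, with 31 to 135 at 2-fold or more, the lowest without NTC replicate 3 or 1 and the highest without ENG_KO replicate 6. The difference of ENG was -0.39 to -0.57 over the left-out libraries. It passed the test without ENG_KO replicate 6, with array weights (-0.57), with length trends removed (-0.50), and with both trends removed, with and without replicate 6 (-0.57 in both). Of the 15 list calls 0 held with an estimated correlation and 2 with fry, which also called the p53 targets, 3 lists in all.

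Directions were counted as reversed only where a value of either sign passed its threshold. That held for genes not called with all 6 libraries, whose differences with array weights, without ENG_KO replicate 6, and with trends removed and that library left out were -0.24, -0.28 and -0.27 for ID3 (-0.25 with trends removed and all libraries), -0.22, -0.25 and -0.24 for EGFL7, 0.25, 0.25 and 0.24 for THBS1, 0.32, 0.30 and 0.28 for JAG1, and -0.23, -0.27 and -0.27 for RFNG. For THY1 the last 2 were -0.13 and -0.13, for RPL37 -0.15 and -0.17, and for RPS28 the first 2 were -0.30 and -0.30. Over the left-out libraries these genes ranged from -0.28 to 0.24 (ID3), -0.25 to 0.46 (EGFL7), -0.17 to 0.25 (THBS1), -0.21 to 0.30 (JAG1), -0.27 to 0.18 (RFNG), -0.13 to 0.23 (THY1), -0.15 to 0.56 (RPL37) and -0.30 to 0.55 (RPS28). The adjusted p of the reversed lists in the same order was 0.0397, 0.0121 and 0.0202 for angiogenic genes, 0.279, 0.0193 and 0.00203 for ribosomal proteins, and 0.964 under the last setting for ion channels. Over the left-out libraries it ranged from 0.0121 to 0.926 for angiogenic genes and from 4.38e-06 to 0.0193 for ribosomal proteins. The reversals came with a lower weight or the absence of ENG_KO replicate 6, or the removal of its trends. For 119 named genes, 1960 of 2373 other values kept direction and call, 112 lost the call, 279 gained it and 22 reversed; for the 28 lists the numbers were 512 of 587, 58, 10 and 7. Depth is unknown, so limits from counting could not be given.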

Other observations

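The tests on ENG_KO replicate 6 and on ID1 and ID3, and those with split or simulated controls, were chosen after the result was seen; the test on chromosome 21 in replicate 6 and the count of other splits were set before their results.

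Several large changes lay outside the rule for named genes, and these genes were chosen after their values were seen. TRPV2, a cation channel, rose by 2.35 (SE 0.08, adjusted p = 0.00112 from limma), SMOC1, a secreted protein described as a BMP antagonist, by 2.15 (SE 0.11, adjusted p = 0.00277), and G0S2, an inhibitor of triglyceride breakdown, by 2.16 (SE 0.29, adjusted p = 0.0226). CFI, a serum protease that limits complement, fell by 1.85 (SE 0.10, adjusted p = 0.00277), and the complement genes CFB and SERPING1 fell by 0.89 and fell by 0.90 without ENG_KO replicate 6, with all-library adjusted p of 0.111 and 0.163. PIEZO2, a mechanically gated channel, fell by 1.53 (SE 0.25, adjusted p = 0.0463), and NNT, a mitochondrial enzyme that makes NADPH, fell by 1.48 (SE 0.23, adjusted p = 0.0382). Without replicate 6, TLR4, a receptor for bacterial lipopolysaccharide, rose by 1.04 (SE 0.06), against 0.73 with all libraries (adjusted p = 0.395).

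ENG_KO replicate 6 differed from the mean of replicates 4 and 5 with an SD of 0.612 over the 13338 genes with a length and GC content, against at most 0.127 in the other pairs within groups. A control library under a knockout label is argued against: over 2696 genes called without it, with trends removed, its differences from NTC followed those of replicates 4 and 5 with a slope of 0.91 (0.88 to 0.94), and of 0.84 to 0.91 over the 2838 to 3199 genes called when the 2 sides used different NTC libraries. With no change in that library the shared controls gave slopes of -0.01 to 0.07 in 100 simulations, and 0.01 to 0.06 with each NTC library in its place; the share of genes going the same way, 77.7%, decides less, as it reached 70.3% for an NTC library. Length and GC content of the longest annotated transcripts explained 50.4% of the variance of its difference, against 3.0% to 28.7% in the other pairs. A bias of this library may thus be part of the cause. Removing both trends left an SD of 0.427, against at most 0.11 in the other pairs, so the trends as fitted do not account for all of it. The longest annotated transcript need not be the expressed one, so this does not exclude such a bias as the whole cause. RNA degradation, another passage or an added biological difference in that culture stay open, as untested.

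ID1 and ID3, short GC-rich BMP targets of 1233 and 1251 bases, were lower in replicates 4 and 5 and higher in replicate 6 than in NTC. With trends removed, 2 of 2 lay below every NTC library in replicate 6, at -0.52 for ID1 (0.41 as deposited) and -0.20 for ID3 (0.71 as deposited). The rise of both in replicate 6 may therefore be part of its length and GC bias, a hypothesis found and tested on the same data. Higher BMP signaling in that culture would raise the other targets too, and of 12 other tested members 8 lay below every NTC library in replicate 6 and 3 above (median -0.36, 95% bootstrap interval -0.71 to 0.11), which leaves it undecided as deposited. With trends removed 10 lay below and 1 above (median -0.51, -0.99 to -0.27), the direction opposite to higher signaling. Both intervals resample genes of 1 library, so they measure the spread between genes and cannot decide the question for the culture. A difference of ID1 and ID3 alone stays open.

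The median of 95 genes of chromosome 21 with a level of at least 8 was 0.071 higher in ENG_KO replicates 4 and 5 than in NTC, relative to all genes and with trends removed. It was 0.074 in replicate 4 and 0.06 in replicate 5, with 84.2% of the genes higher, and 10000 random gene sets matched on level gave p = 1e-04, the smallest they can give (adjusted p = 0.00115 over 23 chromosomes, permutation test, two-sided). In replicate 6 the median was 0.174, above the upper bound of 0.089 for random sets; with controls not shared, replicates 4 and 5 gave 0.063 to 0.071 and replicate 6 gave 0.157 to 0.179, and each NTC library lay within -0.004 to 0.004 of the others. Extra copies of chromosome 21 in part of the cultured knockout cells are a candidate explanation, but other chromosomes also departed from random sets: 16 and 2 in replicates 4 and 5 (-0.024 and 0.013, adjusted p = 0.00115 and 0.00613), and 4, 16, 22, X and 5 in replicate 6 (-0.091, 0.073, 0.078, -0.068 and -0.046, adjusted p from 0.0023 to 0.046). Their medians were smaller, at most 0.024 and 0.091 in size, and chromosome 16 had opposite signs, so a shift in replicate 6 alone is weak evidence; DNA was not analysed here, and regulation of chromosome 21 genes by loss of ENG stays open, as untested.

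Splitting the 6 libraries into 3 and 3 can be done in 10 ways, too few for a share under 0.05. The real split gave 222 genes and was the only 1 with as many, and the highest of the others gave 0. Each other split puts NTC and ENG_KO libraries in both groups, so their differences widen the spread within groups. Few calls were therefore likely there from the start, and the 0 is no support for the 222 genes.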
